A study of Drosophila melanogaster with 16 samples.

How the data were processed

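RNA was measured in whole wild-type larvae of Drosophila melanogaster that were moved from a low-sugar diet (LSD, 10% yeast) to LSD or to a high-sugar diet (HSD, 10% yeast with 15% sucrose). The labels list 16 libraries and mark 2 of them, HSD 4 h replicate 2 and HSD 8 h replicate 1, as removed outliers; these were not analysed here, which left 14 libraries in 4 groups (LSD at 8 h, n = 4; HSD at 4 h, n = 3; HSD at 8 h, n = 3; HSD at 16 h, n = 4). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA depleted of ribosomal RNA was made into stranded libraries and sequenced as 75 bp single-end reads, in 2 technical sequencing replicates per sample.

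Per the submitters' processing notes, the authors used Trimmomatic, TopHat2 2.1.0, HTSeq and limma. The genome build, the annotation, the strand setting of the counting and the rule by which genes were kept are not given in the sources used here. Values of overlapping, antisense and near-identical genes are therefore uncertain. The authors deposited 1 table of 10128 genes. Its per-library signal values, as deposited by the authors, are read counts divided by an effective library size, and 100% of them came out as whole multiples of 1 read within a tolerance of 0.01 read. The column sums lie between 910679 and 1063358. The same table gives, per the file headers, the authors' log2 fold changes and mean log2 levels, their t and F statistics (scores) and their p-values and adjusted p-values, none of which has a sample of its own. These were used only for counts of genes set beside those computed here.

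Gene identifiers of the table were matched to the Ensembl 115 annotation of BDGP6.54, which held 9990 of the 10128, and 8675 symbols were identical there. Symbols are printed as the table gives them. The whole reads recovered from the steps of the values gave between 16300308 and 25284073 reads per library, and 3 reads in 1 library corresponded to a value of 0.117 to 0.182. Such floors cover counting error only.

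The analysis used limma 3.58.1 in R 4.3.3. Values were tested as log2(value + 0.5) in genes at 1 or more in at least 3 libraries (10114 genes; 14 were left out). All 4 groups entered 1 fit with a mean per group, which left 10 residual degrees of freedom, and the moderated statistics used a trend of variance on mean. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the genes of a comparison, with a threshold of 0.05. There were 6 comparisons: HSD at 8, 4 and 16 h against LSD at 8 h, and 16 h against 4 h, 8 h against 4 h and 16 h against 8 h within HSD. The tests, groups, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. They had been written for CPM values, and because the columns do not sum to a common total the values are treated as a signal scaled by the authors, with the same test.

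The rule named cwo, sug, cbt, Mondo and bigmax in every comparison with LSD. It also named the 8 largest rises and the 8 largest falls in those comparisons (5 and 5 within HSD) among called genes whose groups did not overlap and whose higher group had a mean of at least 5. Finally it named the 3 members with the smallest adjusted p of each list that passed (2 within HSD) and of the regulator, glycolysis, fatty acid synthesis and clock lists. Where the text gives examples, the other named genes are summarised in counts. Members cited with a log2 difference alone, such as Thor or the maltases, and the gene families among the other observations were chosen after their values were seen.

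A set of 27 gene lists held 447 written genes, of which 381 were measured, with at least 3 measured members each. Lists were tested with limma's camera (correlation between genes preset at 0.01), with camera at an estimated correlation, and with fry, each adjusted over the 27 lists. Fry tests whether the genes of a list move one way and does not compare them with other genes. Members were counted over all genes and adjusted over the list alone. Overlap between comparisons that share the LSD libraries was set beside 20 simulations of unchanged groups and beside 6 assignments of the LSD libraries to separate comparisons.

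Alternatives covered the pseudocount, the filter on low values, median-of-ratios scaling, quantile normalization, a fit of only the groups compared, a fit without trend, library weights, a replicate block, stricter thresholds and leaving out each library in turn. EdgeR 4.0.16 (quasi-likelihood test) was run on the recovered reads as another alternative. It called 3452 genes for HSD at 8 h against LSD, 2440 at 4 h and 3984 at 16 h, of which 3408, 2396 and 3931 were called in the same direction by limma. Within HSD it called 3582 genes for 16 h against 4 h, 878 for 8 h against 4 h and 2942 for 16 h against 8 h. The fit was tested on simulated data for HSD at 8 h against LSD over 10017 genes, in which it recovered 18% of 50 genes changed 1.3-fold, 56% of 50 changed 1.5-fold, 88% of 50 changed 2-fold and 94% of 50 changed 4-fold. Of 140 simulated calls 3 were false. In the simulation 9799 of the 10017 genes were unchanged and genes were drawn independently. The real comparison called 3479 genes, so these shares do not give the sensitivity or the error of the real calls. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.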

Results

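RNA from whole wild-type Drosophila melanogaster larvae was sequenced after a change of diet. Larvae were reared on a low-sugar diet (LSD, 10% yeast) and, early in the second instar, were moved either to LSD again or to a high-sugar diet (HSD, 10% yeast with 15% sucrose). HSD larvae were sampled after 4, 8 and 16 h and LSD larvae after 8 h, so diet was separated from time at 8 h alone. The table held normalised read counts of 10128 genes in 14 libraries, of which 4 were LSD at 8 h, 3 HSD at 4 h, 3 HSD at 8 h and 4 HSD at 16 h. A further 2 libraries, HSD 4 h replicate 2 and HSD 8 h replicate 1, were marked in the labels as removed outliers and were not analysed here. The reads counted in LSD replicates 1 to 4 were 25284073, 21044449, 19926443 and 16300308. Those in HSD at 4 h (replicates 1, 3 and 4) were 18631083, 24370459 and 17125595, and those in HSD at 8 h (replicates 2, 3 and 4) were 17801048, 18662525 and 20379660. HSD at 16 h had 20407081, 22209115, 20012950 and 19443170 reads in replicates 1 to 4.

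The 10 most abundant genes took 10.6% to 16.0% of the reads of a library, and 3 reads corresponded to a normalised read count of 0.117 to 0.182. Within groups, Pearson's r across genes lay between 0.971 and 0.992 over 18 pairs of libraries, and every pair differed by more than sampling noise (chi-square per degree of freedom 13 to 101). LSD replicates 2 and 3 and HSD 16 h replicate 2 were rich in many cuticle transcripts, with TwdlJ at 17.4, 33.6 and 12.5 against 0 to 0.938 in the other libraries of their groups. The median log2 deviation of the cuticle list was 1.0971, 0.7197 and 0.2097 in them. It was 0.0554 and 0.0527 in LSD replicates 1 and 4 and -1.1173 to -0.8264 in the other HSD 16 h libraries. Not every cuticle gene followed: TwdlO was lower in these 3 libraries, at 1.256, 4.502 and 31.3. It lay at 14.57 and 25.98 in LSD replicates 1 and 4 and at 38.29 to 74.17 in the other HSD 16 h libraries. Leaving out LSD replicates 2 and 3 and HSD 16 h replicate 2 was an alternative chosen after the data were seen. It kept the HSD 8 h libraries, where TwdlJ lay at 15.8 to 42.4, so at 8 h it set LSD libraries low in cuticle transcripts against HSD libraries high in them. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Values below are mean normalised read counts ± SD over the libraries of a group (n = 4 for LSD and for HSD at 16 h, n = 3 for HSD at 4 h and at 8 h). Log2 differences, with their SE, are on the log2(value + 0.5) scale, which understates the change of low genes. Folds are these log2 differences turned back to a ratio, so they can differ from the ratio of the printed means, most of all in low genes. Adjusted p-values of genes are from limma over 10114 genes, and those of gene lists are from limma's camera test over 27 lists. Of 54 list calls 0 held when the correlation between genes was estimated, which gave the highest adjusted p of all alternatives for each of the 54. Positions are those of BDGP6.54 and were matched through the gene identifiers.

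The comparison of HSD with LSD at 8 h was matched for time on the diet, but a match in molt stage was not shown. TwdlJ lay at 0.938, 17.4, 33.6 and 0.727 in LSD replicates 1 to 4. In HSD 8 h replicates 2, 3 and 4 it lay at 35.9, 15.8 and 42.4. The differences below can therefore hold a difference in molt stage besides the response to sugar. The transcription factor gene sugarbabe (sug, FBgn0033782, 2R 12924567 to 12930644) rose 8.67-fold, from 11.2 ± 1.18 (n = 4) to 101 ± 11.6 (n = 3; log2 3.12, SE 0.10, adjusted p = 1.33e-09). Cabut (cbt, FBgn0043364, 2L 476446 to 479688), a repressor gene known to respond to sugar, rose 2.71-fold, from 47.3 ± 6.34 to 128 ± 9.68 (adjusted p = 5.72e-07). The sugar-sensing factor Mondo (FBgn0032940, 2L 21286078 to 21310050) rose 2.12-fold, from 127 ± 12.1 to 268 ± 3.34 (adjusted p = 9.19e-07). Its partner bigmax (FBgn0039509, 3R 27287366 to 27288526) rose 1.54-fold, from 14.5 ± 2.21 to 22.5 ± 2.48 (adjusted p = 0.0031). The activin ligand gene daw (FBgn0031461) rose 3.42-fold, from 17.1 ± 2.49 to 59.2 ± 2.40. In the reference annotation sug overlaps CG13319, cbt overlaps ush and bigmax overlaps CG3368, and the strand setting of the read counting is not given in the sources used here.

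The gene named in the series title, clockwork orange (cwo, FBgn0259938, 3R 10388258 to 10400752), a repressor of the circadian clock, rose 1.19-fold at 8 h, from 78.9 ± 7.77 (n = 4) to 93.8 ± 2.14 (n = 3; log2 0.25, SE 0.09, adjusted p = 0.0461). This call was close to the threshold, and the adjusted p of cwo at 8 h ranged from 0.00919 to 0.132 over 26 alternatives. It ended when LSD replicate 1 (0.121), 3 (0.104) or 4 (0.0608), HSD 4 h replicate 1 (0.05) or 4 (0.0585), HSD 8 h replicate 2 (0.0831), 3 (0.122) or 4 (0.106), or HSD 16 h replicate 1 (0.0514), 2 (0.0549) or 4 (0.0601) was left out. It also ended under quantile normalization (0.132), with only the groups compared in the fit (0.0714), without trend (0.052), with a replicate block (0.0981) and with edgeR's quasi-likelihood test (0.0511). The level of cwo was 93.5 ± 6.95 in HSD at 4 h (n = 3; log2 0.25, SE 0.09, adjusted p = 0.0669, 0.0217 to 0.234 over the alternatives) and passed the threshold there without LSD replicate 2 (0.0217) or HSD 16 h replicate 3 (0.0344) and with array weights (0.0272). It was 82.6 ± 8.68 in HSD at 16 h (n = 4; log2 0.07, adjusted p = 0.562).

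**Figure D1:**
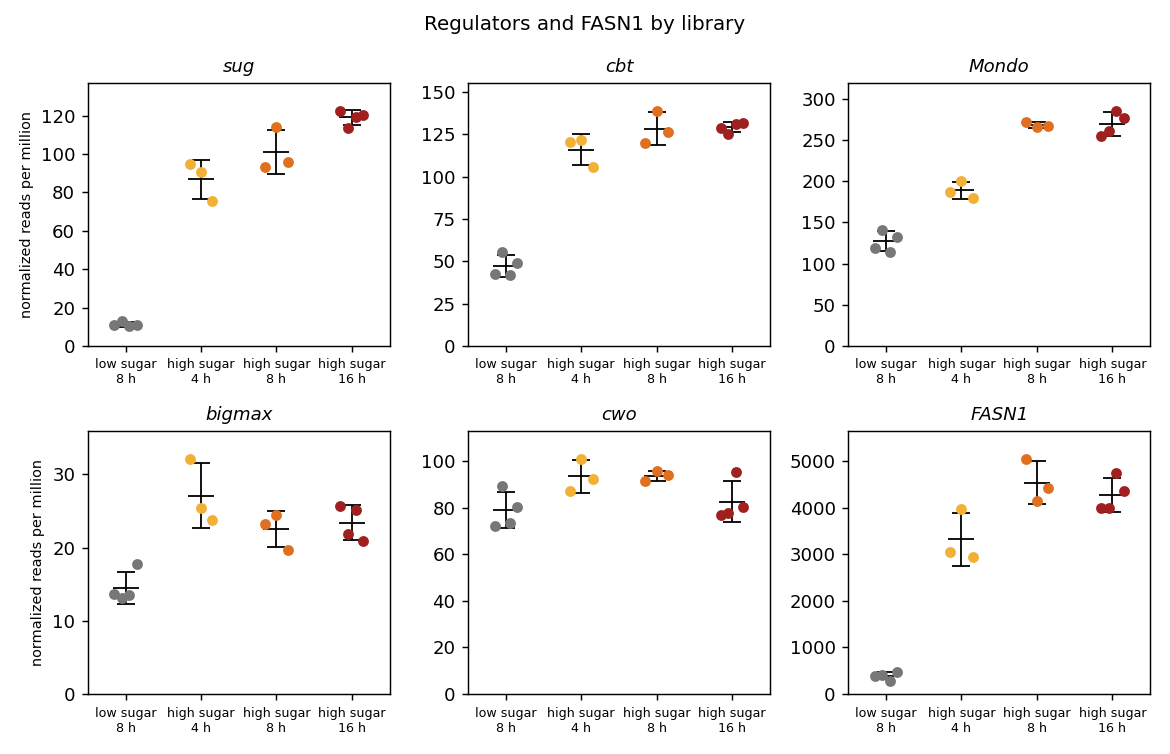
Normalised read counts (linear vertical axis from 0) of sug, cbt, Mondo, bigmax, cwo and FASN1 in each library of LSD at 8 h and HSD at 4, 8 and 16 h. Points are libraries and bars are the group mean ± SD; sug lies at 11.2 on LSD and at 86.8, 101 and 119 on HSD, while cwo lies at 78.9 on LSD and at 93.5, 93.8 and 82.6 on HSD.

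Of the 16 measured sugar-responsive and Mondo-Mlx regulators, 10 rose and 0 fell at 8 h (12 and 0 adjusted over the list alone). The list's median log2 difference was 0.37 (camera adjusted p = 2.85e-05, adjusted p = 0.357 with an estimated correlation). Of the 8 measured clock genes 3 rose and 0 fell (3 and 0 adjusted over the list alone), and the list did not pass (median 0.14, adjusted p = 0.352), except with fry (0.00557). Besides cwo, these were timeless (tim, FBgn0014396), from 3.02 ± 1.06 to 6.30 ± 1.3 (adjusted p = 0.00426), and shaggy (sgg), from 150 ± 11 to 174 ± 10.6 (adjusted p = 0.0211, 0.00802 to 0.103 over the alternatives). The call of sgg ended without LSD replicate 1 (0.0604) or 3 (0.0511) or HSD 8 h replicate 2 (0.103), under quantile normalization (0.0619), with only the groups compared in the fit (0.0924) and without the 3 cuticle-rich libraries (0.0665).

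Genes of fatty acid synthesis and of the pentose phosphate pathway rose at 8 h. Fatty acid synthase 1 (FASN1, FBgn0283427, 2L 3056598 to 3068177) rose 11.7-fold, from 392 ± 79.5 (n = 4) to 4535 ± 464 (n = 3; log2 3.55, SE 0.16, adjusted p = 1.76e-08). Acetyl-CoA synthetase (AcCoAS, FBgn0012034) rose 5.92-fold, from 231 ± 34.1 to 1358 ± 33.7, and the desaturase Desat1 (FBgn0086687) rose 4.77-fold, from 356 ± 36.3 to 1692 ± 55.0. Of 16 measured genes of fatty acid and triglyceride synthesis, 11 rose and 1 fell (13 and 1 adjusted over the list alone; median 0.79, camera adjusted p = 1.39e-09, adjusted p = 0.172 with an estimated correlation). The gene that fell was FASN3, by a log2 difference of -0.34. All 7 measured pentose phosphate genes rose under both adjustments (7 adjusted over the list alone; median 1.19, camera adjusted p = 5.05e-08, adjusted p = 0.163 with an estimated correlation). Among them Pgd (FBgn0004654) rose 3.70-fold, from 113 ± 6.28 to 420 ± 2.32, and Zw (FBgn0004057) rose from 47.5 ± 6.30 to 153 ± 5.92.

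Glycolysis moved less. Of 14 measured genes 6 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.12, camera adjusted p = 0.025, adjusted p = 0.622 with an estimated correlation). Pyruvate kinase (PyK, FBgn0267385) rose 1.63-fold, from 845 ± 40.4 (n = 4) to 1380 ± 20.1 (n = 3), Pfrx rose from 48.1 ± 10.2 to 115 ± 10.7, and lactate dehydrogenase (ImpL3) fell by 0.55 on the log2 scale. In trehalose and glycogen metabolism 5 of 10 genes rose and 1 fell (6 and 1 adjusted over the list alone; median 0.21, camera adjusted p = 0.025, adjusted p = 0.499 with an estimated correlation), and quantile normalization ended the call (0.108). In that list Tps1 rose from 171 ± 39.1 to 382 ± 14.2. Of 10 sugar transporters 5 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.53, camera adjusted p = 0.03, adjusted p = 0.576 with an estimated correlation). CG1213 rose from 14.5 ± 2.06 to 66.5 ± 12.9 and sut1 fell by 1.57 on the log2 scale. The transporter list no longer passed without LSD replicate 3 (0.0726), HSD 8 h replicate 2 (0.0505) or the 3 cuticle-rich libraries (0.139), nor with array weights (0.0525).

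Of 28 gut serine proteases 25 rose and 0 fell at 8 h (25 and 0 adjusted over the list alone; median 1.31, camera adjusted p = 1e-09, adjusted p = 0.445 with an estimated correlation). Trypsin iotaTry (FBgn0015001) rose 3.92-fold, from 7.27 ± 3.83 (n = 4) to 27.6 ± 2.72 (n = 3). Of 21 detoxification genes 13 rose and 0 fell (13 and 1 adjusted over the list alone; median 0.51, camera adjusted p = 1.47e-05, adjusted p = 0.357 with an estimated correlation). GstE7 rose from 25.6 ± 3.84 to 71.5 ± 4.90. Serine, one-carbon and amino acid synthesis had 7 of 13 genes higher and 2 lower (7 and 2 adjusted over the list alone; median 0.30, camera adjusted p = 0.00333, adjusted p = 0.358 with an estimated correlation). Glutamine synthetase Gs1 rose from 284 ± 18.6 to 779 ± 58.6.

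Of the 11 lists that passed at 8 h, 2 were lower. Of 18 nucleolar and ribosome biogenesis genes 17 fell and 1 rose (17 and 1 adjusted over the list alone; median -0.77, camera adjusted p = 1.39e-09, adjusted p = 0.357 with an estimated correlation). The snoRNP protein gene nop5 (FBgn0026196) fell from 237 ± 30.0 (n = 4) to 120 ± 8.74 (n = 3) and Nop60B (FBgn0259937) from 327 ± 43.9 to 155 ± 17.8, while Non1 rose by a log2 difference of 0.53. In amino acid catabolism 7 of 12 genes fell and 0 rose (7 and 1 adjusted over the list alone; median -0.49, camera adjusted p = 0.00358, adjusted p = 0.172 with an estimated correlation). Ornithine aminotransferase (Oat) fell from 218 ± 33.2 to 108 ± 21.4. Near-identical trypsin and amylase copies could share reads, so values of single copies are uncertain.

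The other 15 lists did not pass at 8 h besides the clock genes. Fatty acid oxidation and lipolysis had 3 of 16 genes higher and 4 lower (median -0.01, adjusted p = 0.729), and gluconeogenesis had 2 of 6 higher (median -0.03, mean 0.20, adjusted p = 0.534). In the insulin, AKH and FOXO list 5 of 15 genes were higher and 2 lower (median -0.04, mean 0.18, adjusted p = 0.353). Thor and AkhR were higher there, by log2 differences of 1.61 and 1.53. With fry the gluconeogenesis and insulin lists passed (0.0156 and 0.00382). Carbohydrate digestion had 5 of 19 genes higher and 2 lower (median 0.48, adjusted p = 0.119, 0.0261 to 0.801 over the alternatives) and passed without LSD replicate 2 (0.0261) and with array weights (0.0273). Gut lipases had 1 of 10 higher and 5 lower (median -0.66, adjusted p = 0.528). Antimicrobial peptides and immune effectors had 2 of 18 higher and 1 lower (median 0.01, mean -0.11, adjusted p = 0.729), and heat shock proteins 2 of 9 lower (median -0.43, adjusted p = 0.297). The ecdysone list had 1 of 22 genes higher and 1 lower (median -0.01, mean 0.07, adjusted p = 0.729) and the cuticle and molting list 2 of 34 higher (median 0.28, adjusted p = 0.352). Without the 3 cuticle-rich libraries, which were chosen by a cuticle gene, the cuticle list passed (median 0.67, adjusted p = 0.0067), so this value does not test that list. Of tissue markers, fat body genes had 1 of 6 lower (median 0.20, mean 0.09, a test direction of lower, adjusted p = 0.957). Muscle markers had 2 of 15 higher and 3 lower (median -0.12, adjusted p = 0.467) and neuron markers 1 of 13 higher and 6 lower (median -0.14, adjusted p = 0.2, 0.0464 without the 3 cuticle-rich libraries). Salivary gland markers had 1 of 7 higher and 1 lower (median 0.14, adjusted p = 0.729) and testis markers 0 of 5 either way (median 0.37, adjusted p = 0.417). Hemocyte markers had 1 of 13 higher (median 0.41, adjusted p = 0.0997, 0.013 to 0.792 over the alternatives). The hemocyte list passed without LSD replicate 2 (0.0261), HSD 4 h replicate 4 (0.0232), HSD 8 h replicate 3 (0.0333) or the 3 cuticle-rich libraries (0.0468), and with only the groups compared in the fit (0.013). The test direction was higher for the gluconeogenesis, insulin, immune and ecdysone lists.

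**Figure D2:**
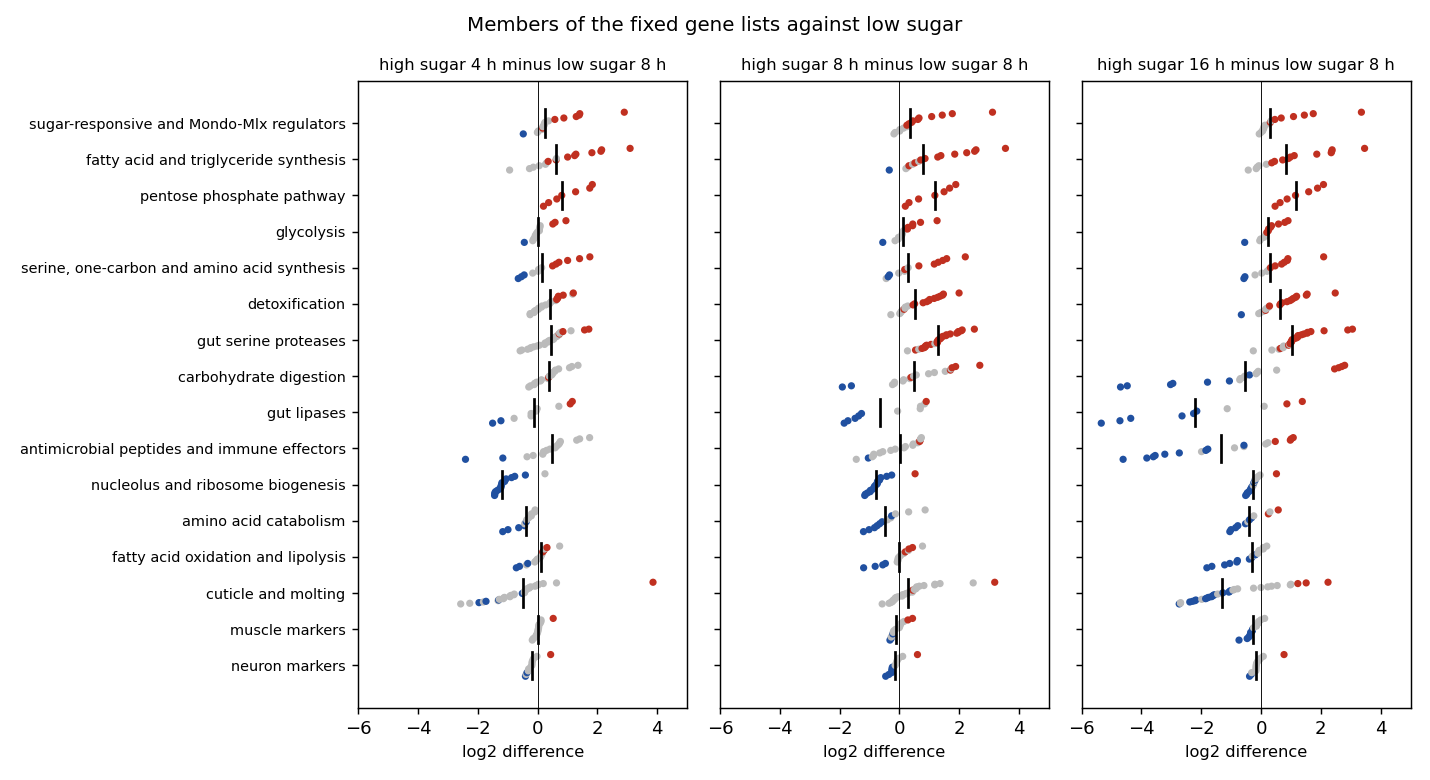
Log2 difference of each measured member (horizontal axis, log2(value + 0.5) scale) for 16 of the fixed gene lists in the comparisons of HSD at 4, 8 and 16 h with LSD at 8 h. Each dot is a gene, red where it was higher, blue where it was lower and grey where it did not pass, and the black bar is the list's median, which for the nucleolar list is -1.21, -0.77 and -0.26 at 4, 8 and 16 h.

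Single genes with the largest rises at 8 h included CG1774 (FBgn0039856, 3R 31592803 to 31594719), which rose 16.1-fold from 34.8 ± 7.63 (n = 4) to 560 ± 34.5 (n = 3; log2 4.01, SE 0.13, adjusted p = 1.33e-09). CG14205 (FBgn0031034) rose from 31.1 ± 29.9 to 362 ± 40.7, CG15534 (FBgn0039769) from 9.90 ± 7.01 to 104 ± 14.3, and CG12057 (FBgn0030098) from 3.17 ± 1.69 to 52.9 ± 12.8. CR45190 (FBgn0266700), annotated as antisense to CG1635, was near the 3-read level on LSD (0.205 ± 0.162) and at 11.7 ± 0.789 on HSD. CG32266, CG14564 and Npc2c completed this group of 8, from 5.15 ± 5.74, 2.89 ± 3.61 and 2.00 ± 1.1203 on LSD to 61.5 ± 39.8, 27.7 ± 13.2 and 29.8 ± 14.1 on HSD. In the cuticle-rich LSD replicates 2 and 3 CG32266 lay at 6.63 and 12.7 (0.781 and 0.545 in replicates 1 and 4) and CG14564 at 3.77 and 7.63 (0.0391 and 0.121). The largest falls were those of CG15369 (FBgn0030105), from 14.1 ± 4.60 to 1.07 ± 0.303, and sarcosine dehydrogenase (Sardh, FBgn0034276), from 50.05 ± 12.2 to 6.21 ± 1.35 (log2 -2.91, SE 0.21, adjusted p = 1.28e-06). The odorant-binding protein gene Obp99a (FBgn0039678) fell from 153 ± 18.5 to 34.3 ± 2.30 and CG13962 (FBgn0032824) from 37.6 ± 1.91 to 9.46 ± 0.490. CG13230, CG10026, Cyp28d1 and CG10474 completed the 8 largest falls, with log2 differences of -2.25, -2.22, -1.93 and -1.91.

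In all, 1772 genes rose and 1707 fell at 8 h, of which 359 and 101 changed at least 2-fold, and the median fold among them was 1.37. Under quantile normalization the split was 1500 higher and 1962 lower. The libraries of both groups did not overlap for 3816 genes (37.7%, against 5.71% by chance). The authors' deposited table called 1766 genes higher and 1689 lower, and 3430 genes were called in the same direction there and here.

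The comparison of HSD at 4 h with LSD at 8 h differed in diet and in time. Sug rose 7.45-fold to 86.8 ± 10.2 (n = 3; log2 2.90, SE 0.10, adjusted p = 3.93e-09), cbt rose 2.45-fold to 116 ± 9.04, Mondo 1.49-fold to 189 ± 10.7 and bigmax 1.84-fold to 27.1 ± 4.43. Of the 16 regulators 7 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.23, camera adjusted p = 1.62e-05, adjusted p = 0.37 with an estimated correlation). Myc fell by 0.48 on the log2 scale. All 7 pentose phosphate genes rose (7 adjusted over the list alone; median 0.81, camera adjusted p = 1.65e-08, adjusted p = 0.121 with an estimated correlation). Pgd reached 403 ± 22.0. In fatty acid and triglyceride synthesis 9 of 16 genes rose and 0 fell (11 and 1 adjusted over the list alone; median 0.62, camera adjusted p = 5.11e-07, adjusted p = 0.21 with an estimated correlation). FASN1 rose 8.53-fold to 3322 ± 567.

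The fall of nucleolar genes was deepest at 4 h. Of 18 genes 17 fell and 0 rose (17 and 1 adjusted over the list alone; median -1.21, camera adjusted p = 1.34e-16, adjusted p = 0.207 with an estimated correlation). In this list nop5 fell 2.54-fold to 92.1 ± 3.38 (n = 3; log2 -1.35, SE 0.10, adjusted p = 2.25e-06) and Nop60B 2.70-fold to 120 ± 6.94. In amino acid catabolism 5 of 12 genes fell (7 adjusted over the list alone; median -0.37, camera adjusted p = 0.00206, adjusted p = 0.171 with an estimated correlation). Oat lay at 109 ± 4.52. Of 21 detoxification genes 6 rose (7 adjusted over the list alone; median 0.40, camera adjusted p = 0.022, adjusted p = 0.821 with an estimated correlation). The detoxification list no longer passed without LSD replicate 3 (0.0616) or HSD 4 h replicate 3 (0.101). In the cuticle and molting list 1 of 34 genes rose and 4 fell (1 and 3 adjusted over the list alone; median -0.48, camera adjusted p = 0.027, adjusted p = 0.836 with an estimated correlation). The cuticle call ended without LSD replicate 2 (0.0778) or 3 (0.142) or HSD 4 h replicate 3 (0.0784) or 4 (0.0898), with array weights (0.194) and with fry (0.274). It also ended without the 3 cuticle-rich libraries (median -0.18, 0.449), a choice made on a cuticle gene. Of 13 neuron markers 1 rose and 2 fell (1 and 4 adjusted over the list alone; median -0.19, camera adjusted p = 0.0423, adjusted p = 0.836 with an estimated correlation). The neuron call ended without LSD replicate 1 (0.116) or 4 (0.079) or HSD 4 h replicate 1 (0.0935) or 3 (0.101), under quantile normalization (0.0654), with a replicate block (0.0638) and with fry (0.0887). In the neuron list elav fell from 82.3 ± 3.11 to 64.2 ± 2.81. The other members named there went both ways. Eaat1 was higher, at 59.1 to 74.7 in HSD 4 h libraries against 43.5 to 54.9 on LSD. Lower values were seen for futsch, at 83.7 to 97.1 against 93.4 to 130. Leaving out HSD 4 h replicate 3 lowered the number of passing lists from 8 to 5.

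Clock genes did not pass at 4 h (0 of 8 either way, median 0.06, adjusted p = 0.83), nor did glycolysis (3 of 14 higher and 1 lower, adjusted p = 0.606). Gut serine proteases did not pass either (4 of 28 higher, median 0.46, adjusted p = 0.127, 0.00344 to 0.963 over the alternatives). The protease list passed without LSD replicate 2 (0.0107) or HSD 4 h replicate 4 (0.00344). Among single genes CG1774 rose 11.2-fold to 388 ± 18.2 (n = 3; adjusted p = 8.75e-09) and CG4269 (FBgn0034741) rose from 2.06 ± 0.844 to 23.7 ± 9.37. The larval cuticle protein gene Lcp3 (FBgn0002534) was at 0.129 ± 0.135 on LSD and 8.75 ± 2.82 on HSD. CG10026 fell from 10.7 ± 3.26 to 1.67 ± 0.157 and lectin-24A (FBgn0040104) from 68.7 ± 17.7 to 14.6 ± 3.96. CG9521 (FBgn0030588) fell from 87.5 ± 66.6 to 13.7 ± 3.92 (adjusted p = 0.0146, 0.00679 to 0.0566 over the alternatives), a call that ended without HSD 4 h replicate 3 (0.0566) or the 3 cuticle-rich libraries (0.0552), with only the groups compared in the fit (0.0513) and with array weights (0.051). In all, 1293 genes rose and 1156 fell, 168 and 184 of them at least 2-fold, with 640 higher when only the groups compared entered the fit. The libraries did not overlap for 2928 genes (28.9%, against 5.71% by chance).

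The comparison of HSD at 16 h with LSD at 8 h also differed in diet and in time. Sug rose 10.3-fold to 119 ± 3.76 (n = 4; log2 3.36, SE 0.09, adjusted p = 1.34e-10), cbt 2.73-fold to 129 ± 2.79, and Mondo by a log2 difference of 1.09 to 269 ± 14.1. Bigmax rose 1.60-fold to 23.4 ± 2.38. Of the 16 regulators 7 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.30, camera adjusted p = 9.41e-05, adjusted p = 0.418 with an estimated correlation). All 7 pentose phosphate genes rose (7 adjusted over the list alone; median 1.15, camera adjusted p = 1.12e-08, adjusted p = 0.102 with an estimated correlation). In fatty acid and triglyceride synthesis 11 of 16 genes rose (11 adjusted over the list alone; median 0.82, camera adjusted p = 1.19e-06, adjusted p = 0.389 with an estimated correlation). FASN1 rose 11-fold to 4271 ± 357. In glycolysis 8 of 14 genes rose and 1 fell (10 and 1 adjusted over the list alone; median 0.22, camera adjusted p = 0.00316, adjusted p = 0.522 with an estimated correlation). PyK reached 1467 ± 75.0. Timeless rose from 3.02 ± 1.06 to 7.48 ± 0.831 (adjusted p = 0.000506), and the clock list did not pass (1 of 8 higher, median 0.07, adjusted p = 0.59), except with fry (0.0317).

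Digestive genes moved apart at 16 h. Of 28 gut serine proteases 21 rose and 0 fell (22 and 0 adjusted over the list alone; median 1.04, camera adjusted p = 1.48e-08, adjusted p = 0.516 with an estimated correlation). The trypsin-like yip7 rose from 434 ± 64.0 to 1267 ± 136 (n = 4 in both groups). Of 10 gut lipases 6 fell and 2 rose (6 and 2 adjusted over the list alone; median -2.20, camera adjusted p = 0.00921, adjusted p = 0.516 with an estimated correlation). Requiring a mean value of 5 ended that call (0.0734). CG6283 (FBgn0039474) fell from 62.6 ± 31.8 to 0.880 ± 0.378 (log2 -5.34, SE 0.41, adjusted p = 1.73e-06), CG6271 (FBgn0039476) from 23.7 ± 10.7 to 0.368 ± 0.205 and CG8093 (FBgn0033999) from 20.5 ± 16.2 to 0.328 ± 0.270. The amylase copies Amy-p (FBgn0000079, 2R 17118636 to 17120303) and Amy-d (FBgn0000078, 2R 17124764 to 17126369) fell from 48.2 ± 18 to 1.52 ± 1.34 and from 21.7 ± 9.16 to 0.559 ± 0.684. Carbohydrate digestion did not pass as a list, with 4 of 19 genes higher and 7 lower (4 and 9 adjusted over the list alone; median -0.55, adjusted p = 0.23). The maltases Mal-A1, Mal-A6, Mal-A7 and Mal-A8 rose by log2 differences of 2.60, 2.80, 2.46 and 2.70.

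The list of antimicrobial peptides and immune effectors did not pass at 16 h. Drosomycin (Drs, FBgn0283461) fell from 93.0 ± 37.8 to 3.80 ± 2.34 (n = 4 in both groups; log2 -4.61, SE 0.54, adjusted p = 3.84e-05), and DptB and Mtk fell by 3.82 and 3.60 on the log2 scale. Of 18 immune genes 9 fell and 4 rose (9 and 4 adjusted over the list alone; median -1.33, adjusted p = 0.0795, 0.0139 to 0.627 over the alternatives). The list passed without LSD replicate 3 (0.0489) or HSD 16 h replicate 1 (0.0139), under quantile normalization (0.0367), with a replicate block (0.0389) and with fry (0.0325). In the cuticle and molting list 16 of 34 genes fell and 3 rose (22 and 4 adjusted over the list alone; median -1.29, camera adjusted p = 0.00229, adjusted p = 0.605 with an estimated correlation). The chitin synthase gene kkv (FBgn0001311) fell from 505 ± 78.1 to 162 ± 36.7 and TwdlT (FBgn0029170) from 278 ± 49.97 to 57.2 ± 14.1.

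Fatty acid oxidation and lipolysis had 9 of 16 genes lower at 16 h and 0 higher (10 and 0 adjusted over the list alone; median -0.30, camera adjusted p = 0.00205, adjusted p = 0.389 with an estimated correlation). The acyl-CoA dehydrogenase CG12262 (Mcad) fell from 376 ± 21.8 to 121 ± 22.8 (n = 4 in both groups) and yip2 fell by 1.05 on the log2 scale. Of 21 detoxification genes 14 rose and 1 fell (14 and 1 adjusted over the list alone; median 0.65, camera adjusted p = 4.02e-05, adjusted p = 0.389 with an estimated correlation). In serine, one-carbon and amino acid synthesis 7 of 13 rose and 2 fell (7 and 2 adjusted over the list alone; median 0.32, camera adjusted p = 0.0152, adjusted p = 0.516 with an estimated correlation). In amino acid catabolism 7 of 12 fell and 2 rose (8 and 2 adjusted over the list alone; median -0.41, camera adjusted p = 0.0329, adjusted p = 0.389 with an estimated correlation). The catabolism list no longer passed without LSD replicate 4 (0.0596). Nucleolar genes were closer to their LSD level, with 10 of 18 lower and 1 higher (11 and 1 adjusted over the list alone; median -0.26, camera adjusted p = 0.00921, adjusted p = 0.627 with an estimated correlation). Without the 3 cuticle-rich libraries the nucleolar list did not pass (0.161). Of 15 muscle markers 8 fell and 0 rose (8 and 0 adjusted over the list alone; median -0.28, camera adjusted p = 0.00229, adjusted p = 0.522 with an estimated correlation). Quantile normalization (median -0.05, 0.0527) and leaving out the 3 cuticle-rich libraries (0.0565) ended that call. The list of testis and male germline markers had 3 of 5 genes higher (median 0.53, adjusted p = 0.0643, 0.0213 to 0.587 over the alternatives). Of its 18 written genes 5 were measured, and it was written to include roX1 and roX2, so a shift in it was not tied to testis. This list passed without LSD replicate 2 (0.0407), HSD 4 h replicate 1 (0.0391) or 4 (0.042), HSD 8 h replicate 2 (0.0474) or HSD 16 h replicate 2 (0.0416). It also passed without the 3 cuticle-rich libraries (0.0388), with only the groups compared in the fit (0.0241), with a replicate block (0.0494) and with fry (0.0213).

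**Figure D3:**
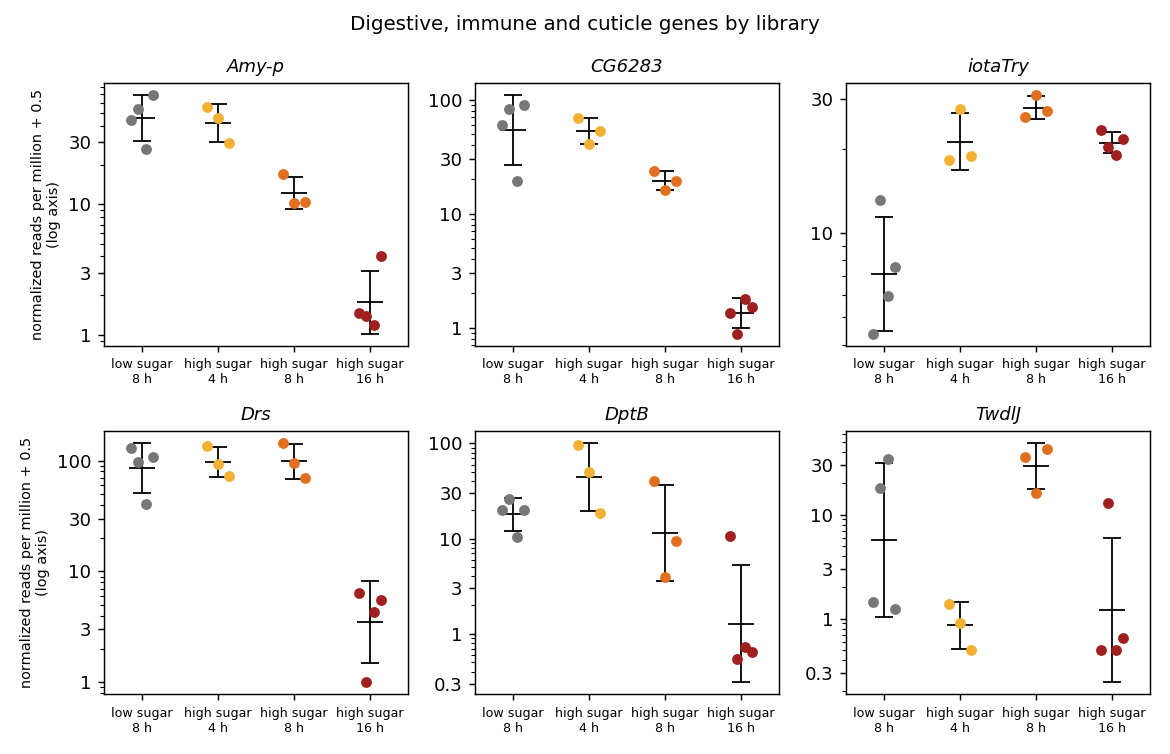
Normalised read counts plus 0.5 (logarithmic vertical axis) of Amy-p, CG6283, iotaTry, Drs, DptB and TwdlJ in each library of LSD at 8 h and HSD at 4, 8 and 16 h. Points are libraries and bars are mean ± SD computed on the log2 scale. The arithmetic means of Amy-p, which the bars do not show, are 48.2 on LSD and 1.52 on HSD at 16 h.

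Among other single genes at 16 h CG1774 rose 21.3-fold to 739 ± 6.26 (n = 4; log2 4.41, SE 0.12, adjusted p = 1.34e-10), and the glucuronosyltransferase gene CG5724 (FBgn0038082) rose from 3.64 ± 2.06 to 75.3 ± 10.7. CR45190 was at 15.6 ± 1.08 and CG4269 at 31.5 ± 3.68. CG34166 (FBgn0085195) fell 19.1-fold, from 907 ± 28.6 to 47.4 ± 6.55, and SPH93 (FBgn0032638) fell from 19.9 ± 8.09 to 0.858 ± 1.32. In all, 1959 genes rose and 2059 fell, 332 and 598 of them at least 2-fold, and the libraries did not overlap for 3687 genes (36.5%, against 2.86% by chance). The split was 2440 higher and 1670 lower under quantile normalization.

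The 3 comparisons shared the LSD libraries. Higher at 8 h and at 4 h were 882 genes, and 861 were lower at both (227 and 195 for independent lists). At 8 h and 16 h these counts were 1136 and 779 (343 and 348 for independent lists), and at 4 h and 16 h they were 739 and 489 (250 and 235 for independent lists). In 20 simulations all libraries, the controls included, were redrawn with the same spread per gene and no group difference, and the number of shared calls was 0 in each. No gene differed in these draws and genes were not correlated, so the 0 does not measure how many calls shared controls can add. With the LSD libraries split into pairs, so that no library served both comparisons, the median counts over 6 assignments were 558 and 619, 745.5 and 480, and 447.5 and 326. Across genes, which are not independent replicates, Pearson's r of the log2 differences was 0.56, 0.54 and 0.50 for these pairs, against simulated ranges of 0.39 to 0.46, 0.42 to 0.52 and 0.42 to 0.51. For 4 h and 16 h r lay within the simulated range, so r by itself does not tell agreement from shared controls there. With the LSD libraries split the median r was 0.47, 0.48 and 0.39 (0.13 to 0.62, 0.21 to 0.60 and 0.33 to 0.45). The covariances were 0.122, 0.178 and 0.145, against simulated means of 0.0196, 0.0200 and 0.0195. With the LSD libraries split the median covariances were 0.108, 0.165 and 0.121, so the shared size of the changes did not rest on shared libraries alone. Genes higher at all 3 times numbered 645 and genes lower at all 3 numbered 434. Called in opposite directions were 20, 39 and 93 genes for these pairs, and 116 of the 6023 genes called at any time had opposite signs among times.

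Within HSD, the comparison of 8 h with 4 h had 476 higher and 455 lower genes, 98 and 25 of them at least 2-fold. These counts depended on single libraries. Without HSD 4 h replicate 1 they were 201 and 149, and without HSD 4 h replicate 4 they were 170 and 161. Without HSD 8 h replicates 2, 3 and 4 they were 183 and 137, 191 and 179, and 234 and 237. Under quantile normalization they were 391 and 638, with a replicate block 97 and 62, and with array weights 980 and 790. Of 28 gut serine proteases 7 rose (16 adjusted over the list alone; median 0.87, camera adjusted p = 1.75e-10, adjusted p = 0.649 with an estimated correlation). The protease yip7 rose from 354.5 ± 115 (n = 3) to 899 ± 70.3 (n = 3). Nucleolar genes rose in 7 of 18 cases (14 adjusted over the list alone; median 0.35, camera adjusted p = 9.19e-08, adjusted p = 0.649 with an estimated correlation). Fatty acid and triglyceride synthesis had 5 of 16 genes higher (9 adjusted over the list alone; median 0.41, camera adjusted p = 0.000287, adjusted p = 0.649 with an estimated correlation). Malic enzyme (Men) rose from 1357 ± 29.6 to 2158 ± 119. Detoxification had 3 of 21 higher (6 adjusted over the list alone; median 0.31, camera adjusted p = 0.00117, adjusted p = 0.649 with an estimated correlation). GstD1 rose from 718 ± 16.8 to 1002 ± 9.17.

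Serine, one-carbon and amino acid synthesis had 4 of 13 genes higher and 1 lower at 8 h than at 4 h (5 and 1 adjusted over the list alone; median 0.21, camera adjusted p = 0.0219, adjusted p = 0.664 with an estimated correlation). That call ended without HSD 8 h replicate 2 (0.0552). Cuticle genes had 4 of 34 higher (8 adjusted over the list alone; median 0.99, camera adjusted p = 0.000232, adjusted p = 0.724 with an estimated correlation), and the list did not pass with fry (0.116). Hemocyte markers passed with 0 of 13 genes called (0 adjusted over the list alone; median 0.51, camera adjusted p = 0.0269, adjusted p = 0.724 with an estimated correlation). The hemocyte call ended without HSD 4 h replicate 4 (0.243) or HSD 8 h replicate 4 (0.151), when a mean value of 5 was required (0.0861), with only the groups compared in the fit (0.0741) and with fry (0.257). The largest rises were from near the 3-read level at 4 h: CG14564 from 0.0556 ± 0.0964 (n = 3) to 27.7 ± 13.2 (n = 3), CG13068 from 0.0709 ± 0.0362 to 23.5 ± 3.55, and CG13066 from 0.0509 ± 0.0562 to 20.9 ± 6.44. The adjusted p was 0.00589 for CG14564, 0.028 for CG13068 and 0.0459 for CG13066. The calls of CG13068 and CG13066 ended when any 1 of the 6 HSD libraries at 4 h and 8 h was left out (0.0536 to 0.0825 and 0.0792 to 0.125). For CG13066 this was also so without HSD 16 h replicate 1 (0.0571), 3 (0.0528) or 4 (0.0612), with a pseudocount of 0.1 (0.0573) and without trend (0.0527). Both calls ended with a replicate block (0.0835 and 0.132) and with edgeR (0.059 and 0.0786). Over all alternatives the adjusted p ranged from 1.44e-07 to 0.0835 for CG13068 and from 3.33e-06 to 0.132 for CG13066. CG13230 fell from 93.8 ± 24.5 to 12.3 ± 3.5 (adjusted p = 0.00139). Amy-p fell from 43.4 ± 13.5 to 12.1 ± 3.88 (adjusted p = 0.0303, 0.0152 to 0.107 over the alternatives). Its call ended without HSD 4 h replicate 1 (0.107) or 3 (0.0613) or HSD 8 h replicate 2 (0.0518), 3 (0.0978) or 4 (0.0901), and with a replicate block (0.0911). The libraries did not overlap for 3490 genes (34.5%, against 10% by chance).

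From 8 h to 16 h on HSD 1424 genes rose and 1556 fell, 53 and 507 of them at least 2-fold. Without HSD 8 h replicate 2 the number of higher genes was 911, and under quantile normalization the split was 2477 and 1114. Drs fell from 103 ± 38.1 (n = 3) to 3.80 ± 2.34 (n = 4), CG6283 14.5-fold from 19.2 ± 3.78 to 0.880 ± 0.378 and Amy-p 6.93-fold from 12.1 ± 3.88 to 1.52 ± 1.34. Of 34 cuticle genes 19 fell and 2 rose (24 and 2 adjusted over the list alone; median -1.48, camera adjusted p = 3.14e-06, adjusted p = 0.651 with an estimated correlation). In it kkv fell from 443 ± 54.4 to 162 ± 36.7. Carbohydrate digestion had 11 of 19 lower (12 lower and 2 higher adjusted over the list alone; median -0.89, camera adjusted p = 0.00339, adjusted p = 0.651 with an estimated correlation). Lipases had 5 of 10 lower (5 adjusted over the list alone; median -1.31, camera adjusted p = 0.0053, adjusted p = 0.651 with an estimated correlation). Of 18 immune genes 7 fell (7 adjusted over the list alone; median -0.87, camera adjusted p = 0.0142, adjusted p = 0.651 with an estimated correlation), and the call ended when a mean value of 5 was required (0.0868). Fatty acid oxidation fell in 10 of 16 cases (11 lower and 1 higher adjusted over the list alone; median -0.26, camera adjusted p = 0.00056, adjusted p = 0.601 with an estimated correlation). Nucleolar genes rose in 16 of 18 cases (16 adjusted over the list alone; median 0.51, camera adjusted p = 1.53e-07, adjusted p = 0.651 with an estimated correlation). In that list nop5 rose from 120 ± 8.74 to 178 ± 14.9.

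Muscle markers had 4 of 15 genes lower at 16 h than at 8 h (4 adjusted over the list alone; median -0.15, camera adjusted p = 0.00824, adjusted p = 0.651 with an estimated correlation). Quantile normalization ended that call (0.178). Pentose phosphate genes had 3 of 7 higher (4 adjusted over the list alone; median 0.20, camera adjusted p = 0.038, adjusted p = 0.651 with an estimated correlation). The pentose phosphate call ended without HSD 8 h replicate 2 (0.0591) or 3 (0.0621) or HSD 16 h replicate 1 (0.0755). Of the largest rises, CG15597 went from 7.58 ± 8.84 (n = 3) to 64.7 ± 42.8 (n = 4) and Nplp4 (FBgn0040717) from 18.3 ± 12.0 to 112 ± 48.6. TwdlJ (FBgn0039440) fell from 31.4 ± 13.8 to 3.17 ± 6.25 (adjusted p = 0.0195, 0.000122 to 0.102 over the alternatives). The call of TwdlJ ended without HSD 8 h replicate 2 (0.0633) or 4 (0.0675) or HSD 16 h replicate 3 (0.0511), and with edgeR's quasi-likelihood test (0.102). The libraries did not overlap for 4591 genes (45.4%, against 5.71% by chance).

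From 4 h to 16 h on HSD 1683 genes rose and 1946 fell, 171 and 543 of them at least 2-fold, and the split was 2161 and 1553 under quantile normalization. The maltase gene Mal-A6 (FBgn0050360) rose 7.12-fold, from 40.6 ± 19.98 (n = 3) to 269 ± 46.7 (n = 4), and Jon74E (FBgn0023197) 6.37-fold, from 65.4 ± 51.6 to 335 ± 65.0. CG6283 fell from 54.4 ± 14.3 to 0.880 ± 0.378, Drs from 99.4 ± 31.3 to 3.80 ± 2.34 and DptB (FBgn0034407) from 54.2 ± 38.7 to 2.62 ± 4.96. All 18 nucleolar genes rose (18 adjusted over the list alone; median 0.89, camera adjusted p = 2.05e-12, adjusted p = 0.58 with an estimated correlation). Nopp140 (FBgn0037137) rose 2.46-fold from 53.3 ± 5.24 to 132 ± 14.2. Fatty acid oxidation had 10 of 16 genes lower (11 adjusted over the list alone; median -0.39, camera adjusted p = 0.000145, adjusted p = 0.58 with an estimated correlation). Lipases had 7 of 10 lower (7 adjusted over the list alone; median -1.22, camera adjusted p = 0.00189, adjusted p = 0.672 with an estimated correlation). Muscle markers had 10 of 15 lower (10 adjusted over the list alone; median -0.30, camera adjusted p = 0.00151, adjusted p = 0.811 with an estimated correlation). Gut serine proteases had 11 of 28 higher (11 adjusted over the list alone; median 0.60, camera adjusted p = 0.000145, adjusted p = 0.859 with an estimated correlation). Pentose phosphate genes had 5 of 7 higher (5 adjusted over the list alone; median 0.26, camera adjusted p = 0.00936, adjusted p = 0.672 with an estimated correlation). Of 21 detoxification genes 9 rose and 2 fell (12 and 3 adjusted over the list alone; median 0.26, camera adjusted p = 0.0438, adjusted p = 0.859 with an estimated correlation). The detoxification call ended without HSD 4 h replicate 1 (0.0621) or 4 (0.0901), HSD 8 h replicate 3 (0.0511) or HSD 16 h replicate 1 (0.054) or 4 (0.0587). The libraries did not overlap for 4622 genes (45.7%, against 5.71% by chance).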

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

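The explanations in this part, and the values that would argue against each, were set only after the result was seen. The scaling alternatives, the leaving out of single libraries and the comparison of 16 h with 4 h that they draw on had been planned. Nucleolar genes, digestive genes and cuticle genes gave the patterns weighed first, and the remaining results are given as values.

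The nucleolar list differed between times on HSD: its median rose by a log2 difference of 0.886 from 4 h to 16 h, from -1.21 to -0.26 against LSD. Its median at 4 h was -1.1955 under quantile normalization and -1.2092 under median-of-ratios scaling, which argues against the scaling of the libraries. At the matched 8 h it was -0.7691 with 17 of 18 genes lower, which argues against time on the plate alone, and leaving out each LSD library left the median at 4 h at -1.1478 or lower, which argues against 1 low-sugar library setting the level. In single libraries nop5 lay at 192 in LSD replicate 4 against 246.6 to 257.2 in the others, and Fib at 158.6 against 212.1 to 217.4. A response of ribosome biogenesis to the change of diet may stay as a hypothesis. The time since the transfer was matched for LSD and HSD only at 8 h, so the time course of such a response was not tested.

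Digestive genes also differed between 16 h and 4 h: the median of the proteases by 0.6008 (0.46 to 1.04) and that of the lipases by -1.2221 (-0.13 to -2.20). Proteases and lipases stood 3.2423 apart at 16 h with opposite signs, so a gut share that changed alike for both lists could not give both shifts. These values are the pattern itself and no separate test of it. A change in the share of gut regions or cell types was not tested. The summed value of Amy-p and Amy-d changed by -4.9506 (SE 0.5693), so reads moving between the copies do not explain their fall, and 25 of 28 proteases were higher at the matched 8 h, which argues against time alone for that list. The further fall of lipases from 8 h to 16 h (-1.3086) cannot be told apart from time on the plate, because LSD was sampled at 8 h alone. A change of digestive enzyme expression with diet may remain, as a hypothesis for the proteases.

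Cuticle genes differed between libraries of one group. In LSD replicates 2 and 3 TwdlJ lay at 17.43 and 33.58 against 0.9376 and 0.7268 in replicates 1 and 4, and CG13066 at 13.01 and 20.92 against 0.0391 and 0. In HSD 16 h replicate 2 TwdlJ lay at 12.55 against 0 to 0.1466 in the other 3 libraries, CG13051 at 19.26 against 0.09101 to 0.2444, CG13066 at 10.18 against 0, CG13068 at 9.421 against 0 to 0.04888, CG34273 at 9.844 against 0.0455 to 1.466 and Cpr67Fa1 at 21.63 against 6.143 to 7.429. The Tweedle gene TwdlO went the other way, at 1.256 and 4.502 in LSD replicates 2 and 3 against 14.57 and 25.98 in replicates 1 and 4. In HSD 16 h replicate 2 TwdlO lay at 31.3 against 38.29 to 74.17 in the others. The 34 cuticle genes deviated together within groups on average, with a mean pairwise correlation of 0.3455 against at most 0.0865 in 1000 random lists of that size. The list was taken up because its genes were seen to differ, and random genes are no reference for related genes, so this restates the pattern. Pools with different shares of larvae near a molt might give it, which was not tested. Whether diet also shifted the molt cannot be told apart from this, since the list's difference at 8 h (0.2758) lay within the SD of its LSD libraries (0.5168).

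Other single libraries stood apart in groups of 4, where chance marks about 1 in 20 of the 256 gene groups and 54 list groups tested; 25 genes and 2 lists did. Among LSD libraries, bigmax was at 17.81 in replicate 4 (others 13.11 to 13.67), CG8036 at 632.6 in replicate 2 (467.1 to 495.0), AGBE at 87.16 in replicate 1 (97.51 to 99.58), futsch at 93.38 in replicate 3 (126.1 to 130.3) and Tm2 at 2734 in replicate 3 (2154 to 2236). In HSD 16 h replicate 2, CG32266 was at 7.266 (0.4399 to 1.456), CG14564 at 1.521 (0 in the others), daw at 56.1 (58.69 to 59.0) and CG34166 at 57.16 (43.55 to 44.76), and the median deviation of the fatty acid and triglyceride synthesis list was 0.1228 (0.209 to 0.2256). In replicate 3, aay was at 160.7 (137.9 to 140.6), Eaat1 at 93.15 (78.02 to 79.87), CG15597 at 128.1 (34.37 to 49.37) and yip7 at 1064 (1315 to 1360), and the ecdysone list's median was -0.3166 (0.0222 to 0.0521). Replicate 1 had SPH93 at 2.841 (0.169 to 0.2275) and DptB at 10.06 (0.04225 to 0.2275), and replicate 4 had Amy-p at 3.519 (0.6826 to 0.9781) and CG8093 at 0.7332 (0.182 to 0.2112).

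Between 4 h and 16 h on HSD 21 of 33 genes and 7 lists changed, by the limma test of 16 h against 4 h. The same LSD libraries at 8 h stood beside both times and drop out of this difference. It is therefore a change with time on HSD, and a change of the diet effect with time was not tested. That test called 35.9% of all genes. The 33 were the study genes and the largest rises and falls at 4 h or 16 h against LSD, a choice that favours such a change. Besides the lists above, the log2 change was 0.2607 for the pentose phosphate list, -0.3932 for fatty acid oxidation, 0.2608 for detoxification and -0.2991 for muscle markers. Among genes it was 0.4601 for sug, 0.5114 for Mondo, 0.9304 for CG1774, 1.0767 for CR45190, 1.7509 for CG4563, 2.6317 for CG9521, 1.9027 for CG4830, 2.0693 for CG5724, 3.4999 for CG15597, 1.2726 for CG12057 and 2.2337 for CG15534. It was -1.6176 for Lcp3, -1.4207 for CG6067, -5.327 for CG6283, -3.2114 for CG6271, -4.5844 for Amy-p, -4.7842 for Drs, -4.3712 for Amy-d, -4.1386 for CG8093, -3.7509 for CG34166 and -2.5276 for SPH93.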

How the results depend on the processing

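Leaving out the 3 libraries rich in cuticle transcripts was chosen only after the data were seen; every other alternative was planned. It kept the HSD 8 h libraries, which are as rich in them, so it does not test the cuticle list. Among the 228 named gene results and 162 list results no called direction reversed under an alternative that was run. Most of these genes were named for large changes or small adjusted p in the same data. Their stability therefore says little about the other calls. Of the gene results 228 kept their side of the threshold under median-of-ratios scaling and without a filter on low values, 227 with a pseudocount of 0.1 or of 2, 226 under quantile normalization, 226 without trend, 223 with only the groups compared in the fit, 222 with array weights, 222 with edgeR and 214 with a replicate block, where 14 fell short of the threshold. With 1 library left out, 3096 gene values kept their side, 91 fell short of the threshold and 5 passed it. These counts include libraries of groups outside a comparison, which leave its log2 difference unchanged. Of the list results 162 kept their side under median-of-ratios scaling and 150 under quantile normalization, where 8 passed and 4 no longer did. With fry 17 further lists passed and 4 no longer did, and with 1 library left out 2205 list values kept their side, 39 passed and 24 no longer did.

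Passing counts were 0 in each of the 6 comparisons for lists with an estimated correlation, where 3, 4, 2, 2, 0 and 2 lists had an unadjusted p under 0.05 (8 h, 4 h and 16 h against LSD, then 16 h against 4 h, 8 h against 4 h and 16 h against 8 h). A larger correlation widens the test. The preset of 0.01 was assumed, while the 34 cuticle genes had a mean pairwise correlation of 0.3455 within groups. Adjusted p-values at the preset can therefore overstate a list call. Fry passed 14, 9, 18, 9, 6 and 11 lists.

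Stricter thresholds lower counts by construction. With a change of at least 2-fold, higher and lower genes numbered 359 and 101 for 8 h against LSD, 168 and 184 for 4 h, 332 and 598 for 16 h, 171 and 543 for 16 h against 4 h, 98 and 25 for 8 h against 4 h and 53 and 507 for 16 h against 8 h. With an adjusted p under 0.01 these counts were 1112 and 1012 for 8 h against LSD, 1066 and 1164 for 16 h against 4 h, 103 and 71 for 8 h against 4 h and 656 and 854 for 16 h against 8 h, and 686 and 773 for 4 h and 1160 and 1393 for 16 h against LSD.

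With only the groups compared in the fit, 640 genes were higher at 4 h than on LSD; fewer samples then set the spread. Quantile normalization passed 12 lists for 16 h against 4 h and gave 2477 higher genes for 16 h against 8 h, and array weights gave 980 higher and 790 lower genes for 8 h against 4 h; the cause was not tested. With the LSD libraries split, shared higher genes numbered 558 for 8 h and 4 h, 745.5 for 8 h and 16 h and 447.5 for 4 h and 16 h, and shared lower genes 480 for 8 h and 16 h, with fewer controls per comparison.

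Leaving out 1 library gave 5 to 9 passing lists for 4 h against LSD, 170 to 681 higher and 137 to 593 lower genes for 8 h against 4 h, and 911 to 1559 higher genes for 16 h against 8 h. The lowest of these came without HSD 4 h replicate 3, HSD 4 h replicate 4, HSD 8 h replicate 2 and HSD 8 h replicate 2.

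Replicate numbers did not pair the samples: over 18 pairs with the same number, correlations of deviations ran from -0.46 to 0.35 and 6 were above 0.1, and 4 of 14 libraries correlated best with their own number. A fit with the replicate number as a block called 97 higher and 62 lower genes for 8 h against 4 h, and 1467 and 1380 for 8 h against LSD.

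Without the 3 cuticle-rich libraries 1595 genes were higher and 1355 lower at 8 h, and 221 gene results kept their side while 5 did not. The nucleolar list at 16 h then no longer passed (adjusted p = 0.161), nor did Nop60B (0.0716) or Fib (0.0701). The table used here holds 14 of the 16 labelled libraries, so the 2 marked as removed were not analysed here and the alternative that includes them was not run. Depth limits genes near 3 reads per library, and in simulated data at this size 18% of 1.3-fold changes were recovered. Far fewer genes changed in the simulation than were called in the real data, so this share does not give the sensitivity of the real comparisons.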

Other observations

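The families below, the splits of the samples and the test of a shared component were chosen only after the data were seen. The families were formed by symbol prefix, and 11 of them were examined.

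Of 18 aminoacyl-tRNA synthetase genes 16 were lower than on LSD at 4 h, 16 at 8 h and 17 at 16 h (medians -0.40, -0.39 and -0.31; adjusted p = 0.0847, 0.11 and 0.201 with an estimated correlation); under quantile normalization 11 were lower and 1 higher at 16 h. All 32 proteasome subunit genes were lower at 16 h (median -0.40, adjusted p = 0.246 with an estimated correlation), 7 at 8 h and 0 at 4 h. Under quantile normalization 27 were lower at 16 h and 13 at 8 h, where 3 were lower under median-of-ratios scaling and 1 without the 3 cuticle-rich libraries. Of 59 respiratory chain and ATP synthase genes 13, 18 and 39 were higher at 4, 8 and 16 h (medians 0.15, 0.12 and 0.24; adjusted p = 0.737, 0.851 and 0.377 with an estimated correlation), and 9 and 50 at 8 h and 16 h under quantile normalization; without the 3 cuticle-rich libraries 34 and 29 were higher at 4 h and 8 h. Of 17 Osiris genes 16 were lower at 16 h (median -2.22, adjusted p = 0.246 with an estimated correlation) and 0 at 4 h and 8 h. Of 22 V-ATPase subunit genes 0 were called at 4 h, 14 were higher and 1 lower at 8 h, and 14 and 2 at 16 h (adjusted p = 0.621 at 8 h and 0.38 at 16 h with an estimated correlation).

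Cytochrome P450 genes numbered 69, of which 20 were higher and 6 lower at 4 h, 35 and 7 at 8 h and 27 and 15 at 16 h (adjusted p = 0.737, 0.621 and 0.504 with an estimated correlation). Of 26 Tweedle cuticle genes 14 were lower and 1 higher at 16 h, and of 47 Cpr cuticle genes 23 were lower and 3 higher (adjusted p = 0.288 and 0.38 with an estimated correlation). At 4 h 1 and 3 were lower and 0 and 1 higher, and at 8 h 2 and 0 were lower and 2 and 4 higher. Cytoplasmic ribosomal protein genes moved little, with 10 of 82 higher at 4 h, 5 higher and 3 lower at 8 h and 2 higher and 9 lower at 16 h (adjusted p = 0.737, 0.851 and 0.827 with an estimated correlation). At 16 h quantile normalization turned this round, to 10 higher and 5 lower, and at 4 h median-of-ratios scaling and leaving out the 3 cuticle-rich libraries each left 6 higher. Of 72 mitochondrial ribosomal protein genes 4 were higher and 3 lower at 4 h, 15 were lower and 1 higher at 8 h and 15 were higher at 16 h (adjusted p = 0.967, 0.851 and 0.55 with an estimated correlation). Without the 3 cuticle-rich libraries 4 were higher and 4 lower at 8 h and 26 higher at 16 h, and under quantile normalization 20 were lower at 8 h and 25 higher at 16 h. Of 8 Npc2 genes 2 were higher and 2 lower at 4 h, 4 and 3 at 8 h, and 3 and 5 at 16 h.

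A hypothesis is that a shared developmental component, such as the share of larvae near a molt, may run through libraries of one group. The test followed an earlier version that was dropped, and the values per library had been seen by then. Over the 4 LSD and 4 HSD 16 h libraries, the deviation of the cuticle list from its group mean was set beside the correlation, across 10001 genes outside the cuticle families, of the library's deviations with the change from 4 h to 8 h on HSD. Pearson's r was 0.8476 (two-sided exact permutation p = 0.0243 over 576 permutations within groups) and Spearman's rho was 0.83 (exact permutation p = 0.0417). The 10001 genes still held CG13051, CG13066, CG13068 and CG34273, which were high in the cuticle-rich libraries and in HSD at 8 h. The 2 measures were therefore not independent. Because an earlier version was dropped and the values had been seen, these p-values are descriptive and do not test the relation. Without LSD replicate 2 and HSD 16 h replicate 2, the libraries farthest from the median, r was 0.53, so the relation rests in part on them. Cuticle deviations ran from -0.41 in LSD replicate 1 to 0.59 in LSD replicate 2, and the test does not show what the component is.

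Other splits of the same libraries into groups of the same sizes were counted. For HSD at 8 h against LSD 1 of 35 splits, the real one, called as many as 3479 genes (highest other 2394); for 4 h it was 1 of 35 with 2449 (highest other 1506) and for 16 h 1 of 35 with 4018 (highest other 0). Within HSD it was 1 of 35 with 3629 for 16 h against 4 h (highest other 1468) and 1 of 35 with 2980 for 16 h against 8 h (highest other 233). In these 5 comparisons 1 of 35 is the smallest share the splits can give. The shares were not corrected for the number of comparisons, and the splits were chosen after the data were seen. Every other split mixes libraries of both groups, which widens the spread within groups wherever the groups differ. The split counts therefore do not exclude chance. For 8 h against 4 h 10 splits are too few to give a share under 0.05, with 931 genes in the real split and 0 in the highest other.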
